A study of Xenopus laevis x Xenopus muelleri with 6 samples.

How the data were processed

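RNA from testes of sexually mature hybrid frogs was labelled with biotin and hybridised to 1-colour Affymetrix arrays, per the labels' protocols. The samples were grouped by their titles into 3 normal and 3 sex-reversed testes. The deposited table holds log2 expression values that were made with RMA, per the submitters' processing notes. RMA corrects the background, brings the arrays to a shared distribution by quantile normalization and summarises the probes of each probe set. Its version, its options, the chip definition and the way rows were chosen for the table are not given in the sources used here. That the values are log2 was read from their range, 1.93 to 14.4, and from medians per array of 5.25 to 5.31. They are not centred per gene. Quantile normalization removes any shift shared by most genes of an array, so differences are relative to the bulk of the genes. The probes were designed on X. laevis sequence, and X. muelleri alleles may bind them less well, which bears on the level of a probe set and on differences between animals that carry different alleles. Affymetrix control probe sets were absent from the table. No detection calls were used, and 0 columns of other samples were present.

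Gene symbols came from the platform annotation table. Of 11485 probe sets 6798 had exactly 1 symbol, 110 had several and 4577 had none in that table; no gene was named from a probe set with several. The 6798 covered 5790 distinct symbols, and 143 of them carried placeholder names that were not used. No genome was used, so no coordinates are given.

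Each probe set was tested with limma 3.58.1 (lmFit and eBayes, trend and robust off) in R 4.3.3, as sex-reversed minus normal, two-sided, with Benjamini-Hochberg adjustment over all 11485 probe sets and a threshold of 0.05. Confidence intervals of 95% came from the moderated fit. Probe sets past the threshold were also counted at an absolute log2 difference of at least 1. The overall distance between arrays was the root mean square log2 difference, and the mean between groups minus the mean within groups was compared over the 10 splits of the arrays by an exact one-sided permutation test. Gene lists were tested with camera of limma at a preset correlation of 0.01, with 1 value per gene (the probe set with the highest mean over all arrays) and Benjamini-Hochberg adjustment over 24 lists with at least 5 measured genes. Camera with an estimated correlation and fry were run beside it. A list's level on an array was the mean over its genes of the log2 value minus the gene's mean over the 6 arrays.

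The lists, the alternatives and the rule for named genes were fixed before the data were examined. The lists covered spermatogonia and germ line, meiosis, spermatids and sperm, motile cilium, Sertoli cells, steroidogenesis, oocyte and ovary, sex determination, estrogen response, mitotic cell cycle, ribosomal proteins, oxidative phosphorylation, heat shock and stress, blood, immune cells, smooth muscle and peritubular cells, extracellular matrix, endothelium, skeletal muscle, kidney, fat body, interrenal gland, proteasome and glycolysis. The rule named up to 15 genes per direction past the threshold with all arrays of one group above all of the other. Where fewer than 10 passed, it was filled to 10 with the smallest unadjusted p among probe sets of the same kind with an absolute log2 difference of at least 0.5. It further named the 3 members of each list with the largest absolute difference where none passed, and every measured gene of sex determination. A few further genes were named after their values were seen, and the text says so or names them as calls of an alternative setting; the 2 egg yolk genes and the smaller smooth muscle members were also added in this way.

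Both tests were tested on simulated data with the real probe sets' mean levels and with noise drawn from the variances after limma's moderation. In 20 sets with 200 changed among 11485 probe sets, 6.14% of calls were false and 95% of intervals covered the simulated difference. A shift of 0.5 put on the smooth muscle list was recovered in 20 of 20 sets, and other lists were called in 1 of 460 tests. The simulation leaves out any real covariation of genes between arrays: over the 9 other splits of the real arrays, camera called 6 lists in 216 tests.

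Alternatives were the replicate number as a block, median centring, a further quantile normalization, cyclic loess, filters at the median and the 25th percentile of the mean level, trended and robust variance, an unmoderated test, array weights, removal of probe sets named for cross-hybridisation, each array left out, another threshold, another interval bound, Spearman distance, and other set tests and gene summaries. The mean over L and S copies was added after seeing the data. Neither the labels nor the table give a hybridisation or scan batch, so none was tested. The number of arrays, 3 per group, limits the precision: the median half-width of the 95% interval was 0.644 on the log2 scale, and the median residual SD was 0.340.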

Results

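Gene expression was measured in testes of sexually mature hybrid frogs with a Xenopus laevis mother and a Xenopus muelleri father. Of the 6 Affymetrix arrays, 3 held normal testis and 3 held testis of sex-reversed animals, 1 testis sample per array, and the labels call the samples of a group biological replicates. Whether each came from a separate animal is not spelled out, so the p-values measure the spread between these samples. The genetic sex of the sex-reversed animals and the way their sex was reversed are not given in the sources used here. The deposited table holds log2 values of 11485 probe sets, of which 6798 carried exactly 1 gene symbol. Median log2 values per array lay between 5.25 and 5.31. X. laevis keeps many genes in L and S copies, one from each of its ancestral genomes, and cross-hybridisation between such copies cannot be excluded. The comparison asked whether the testis of a sex-reversed hybrid differs in gene expression from that of a normal hybrid male.

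No probe set passed the threshold between sex-reversed and normal testis (limma, adjusted p of 0.05, n = 3 per group). The genes nearest to it were ube3c.S, a ubiquitin ligase, and cdca7l.S, a nuclear protein related to the cell cycle factor CDCA7. The log2 value of ube3c.S was 4.50 ± 0.29 (SD, n = 3) in normal and 7.13 ± 0.08 in sex-reversed testis, a 6.17-fold difference with an adjusted p of 0.0510 in limma. That of cdca7l.S was 6.01 ± 0.54 in normal and 2.89 ± 0.15 in sex-reversed testis, 8.74-fold apart, with an adjusted p of 0.0578 in limma. Its sex-reversed values, 2.75 to 3.05, lay near the lowest value of each array (1.93 to 2.09). Signal over background was not measured, so the size of this fold difference is uncertain. Among 24 gene lists, that of smooth muscle and peritubular cells rose in sex-reversed testis, with a median log2 difference of 0.50 over 13 genes (camera, preset correlation), and the germ cell, Sertoli cell, steroidogenic and oocyte lists did not pass. The call of the smooth muscle list was lost with a correlation estimated from the data (adjusted p = 0.566 with an estimated correlation) and in fry (adjusted p = 0.461), and none of its members passed. The size of the correlation alone did not lose it, since with the estimate of 0.0332 held fixed the adjusted p in camera was 0.00896. A fixed correlation, as in the preset test, takes no account of the 4 residual degrees of freedom.

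The limma fit gave 508 probe sets with an unadjusted p under 0.05, 260 higher and 248 lower in sex-reversed testis, where 574 would be expected with no difference, and the same test without moderation gave 511 and also 0 calls. For 7181 probe sets (62.5%) the 95% interval of the difference lay within 2-fold in either direction, and for 998 (8.69%) within 1.5-fold. The share within 2-fold was 61.7% among probe sets above the median level, 56.0% among those above the 25th percentile and 49.0% without moderation. The median absolute log2 difference was 0.21, and 294 probe sets had group means at least 2-fold apart. In simulated data with 200 changed among 11485 probe sets, the test recovered 15.7% of log2 differences of 1, 88.0% of differences of 2 and 97.4% of differences of 3. These shares hold for noise drawn from the variances after limma's moderation and for 200 true changes, and with fewer changes the adjustment is stricter. In the real data psmc1.L (-2.64) and dynll1.S (-2.17) had an adjusted p of 0.997 in limma, so probe set differences of that size can go uncalled. Whether the RNA differed is not settled by this. Another probe set of dynll1.S differed by 0.09 (95% interval -0.40 to 0.58), and that of psmc1.L by -1.31. The call count depended on the setting. Median centring and array weights each gave 2 calls, ube3c.S and cdca7l.S, and without sex-reversed replicate 3 there were 6, among them etfb.L, eef1a1.S, kansl2.S and psmc1.L, while ube3c.S and cdca7l.S were not among these 6.

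**Figure D1:**
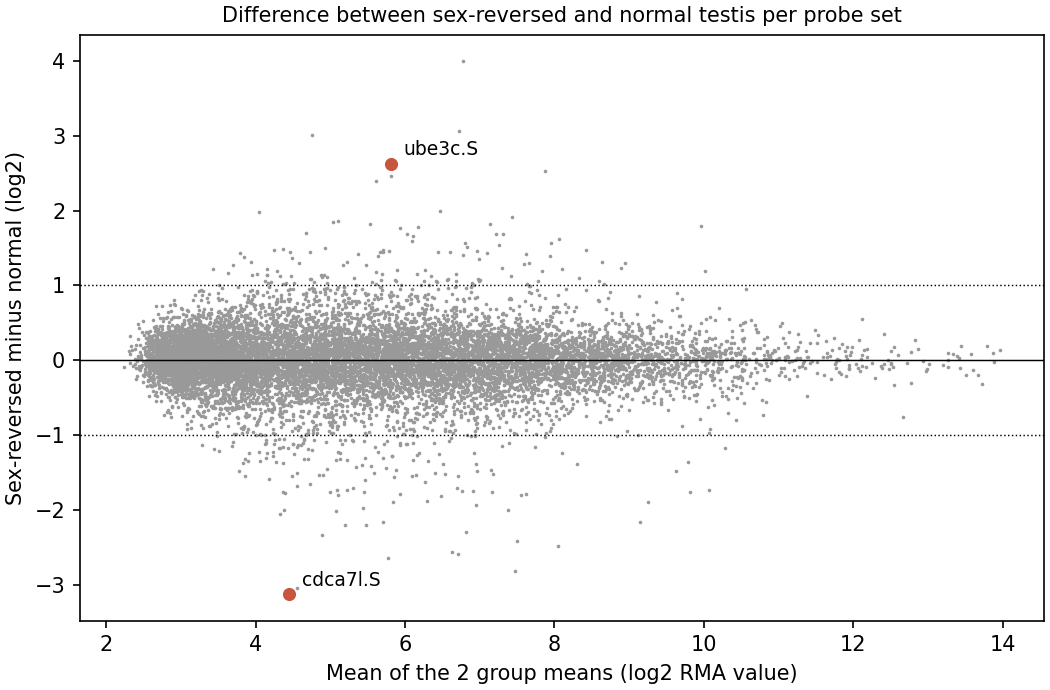
Log2 difference between sex-reversed and normal testis (vertical axis) against the mean of the 2 group means (horizontal axis, log2 RMA value), 1 point per probe set for 11485 probe sets. Dotted lines mark 2-fold; ube3c.S and cdca7l.S, in red, were nearest to the threshold and no probe set passed it.

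Expression profiles of sex-reversed testes lay no farther from those of normal testes than replicates lay from each other. The root mean square log2 difference averaged 0.698 between groups (range 0.620 to 0.740) and 0.701 within groups (range 0.625 to 0.761). An exact one-sided permutation test over the 10 splits of the arrays gave p = 0.5, where 0.1 is the smallest value that 3 against 3 arrays allow. The sign of this small difference depended on single arrays. Between minus within groups was 0.00722 to 0.0160 with any 1 normal replicate or sex-reversed replicate 3 left out. It was -0.0293 and -0.0271 without sex-reversed replicates 1 and 2. Pearson correlations between arrays, taken across probe sets, ran from 0.939 to 0.959. The first principal component held 27.0% of the variance and set normal replicate 2 (38.1) and sex-reversed replicate 1 (25.1) against normal replicate 3 (-30.2) and sex-reversed replicate 3 (-23.8). The second held 23.0% and set sex-reversed replicates 1 (28.95) and 2 (28.75) apart from the normal arrays (-1.03, -37.2 and -8.59). Sex-reversed replicate 3 (-10.9) lay among the normal arrays there.

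Germ cell genes did not pass in either direction. Single-gene values here and in the other groups depend on few arrays: with 1 array left out, the difference moved by over 1.5 times for 61 of 103 named genes and changed sign for 14. Of 15 measured genes of spermatogonia and the germ line, 6 had higher and 9 lower means in sex-reversed testis, with a median log2 difference of -0.09 (camera adjusted p = 0.892). The tudor domain gene tdrkh.L, which acts in the piRNA pathway, differed by 0.78 and by -0.12 once normal replicate 1 was left out. The chemokine receptor gene cxcr4.L differed by 0.67 and id4.S, a marker of spermatogonial stem cells, by -0.53 (-0.25 without sex-reversed replicate 1). Of 5 meiotic genes 1 was higher and 4 lower (median -0.07, adjusted p = 0.752), with brdt.S, a testis bromodomain gene, at -0.88, the synaptonemal complex gene sycp2l.S at 0.27 and the cyclin gene ccna1.S at -0.21. Among 9 spermatid and sperm genes 5 were higher and 4 lower (median 0.08, adjusted p = 0.659). The meiotic list held 50 symbols and the spermatid and sperm list 81, so few of their genes were measured. Group means of meig1.S, ropn1l.L, sp5.S, odf3.S and odf3.L lay between 2.64 and 3.33, low against array medians of 5.25 to 5.31. Signal over background was not measured, so these lists do not show that the 2 kinds of testis are alike. The sperm tail genes tekt4.S and spag6.L differed by 0.58 and 0.54, and septin12.S by 0.43; without normal replicate 2 the value of tekt4.S was -0.11. The 23 genes of the motile cilium were 11 higher and 12 lower (median -0.04, adjusted p = 0.749). Of these, dydc1.L differed by -1.54 (95% interval -2.64 to -0.43) and cfap52.L by 1.42 (95% interval -2.74 to 5.57; 0.29 without normal replicate 3 and 0.35 without sex-reversed replicate 2). The dynein light chain gene dnali1.S differed by 1.29, and by 0.58 without normal replicate 1.

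The somatic cells of the testis were represented in part, by 9 Sertoli cell genes and 14 genes of steroid and cholesterol synthesis, and neither list passed. Of 7 genes of the steroid list that few other cells use, 0 were measured. Among the Sertoli cell genes, dhh.S, dhh.L, gata4.S and sox10.L had group means of 2.68 to 3.46, low against array medians of 5.25 to 5.31. Sertoli cell genes were 5 higher and 4 lower in sex-reversed testis, with a median of 0.03 but a mean of -0.07 and a test in the lower direction (adjusted p = 0.752). The signalling gene dhh.S differed by -0.49 (-0.01 without normal replicate 1), its other copy dhh.L by 0.25 (-0.10 without sex-reversed replicate 3) and the gap junction gene gja1.L by -0.36. Steroidogenic genes were 5 higher and 9 lower (median -0.13, adjusted p = 0.734). For cyp17a1.L, the enzyme that leads from pregnenolone and progesterone to androgens, the log2 difference was -1.77 with a 95% interval of -5.09 to 1.56. That value rested on sex-reversed replicate 3, at 5.17 against 9.96 to 11.3 on the other arrays, and without it the difference was 0.12. A second probe set of cyp17a1.L read 5.23 on that array and 8.14 to 8.93 on the others. The cholesterol transport gene stard3.S differed by -0.50 and the reductase gene srd5a3.S by -0.36.

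Genes of sex determination and gonad development also did not pass, with 8 of 17 higher and 9 lower (median -0.11, adjusted p = 0.752). The testis factor sox9.S, at 6.74 ± 0.52 (SD, n = 3) in normal and 6.50 ± 0.57 in sex-reversed testis, differed by -0.24 with a 95% interval of -1.11 to 0.64. Differences were -0.51 for the protease gene capn5.L and 0.56 for its other copy capn5.S (0.23 without normal replicate 2), -0.43 for sox3.S, 0.20 for sox3.L, 0.33 for emx2.L (0.005 without sex-reversed replicate 3) and 0.19 for gata4.S. The estrogen receptor copies esr1.L and esr1.S lay at -0.15 and 0.08, cbx2.L at -0.16, and fst.L and lhx9.L both at 0.07. The beta-catenin copies ctnnb1.L and ctnnb1.S lay at -0.11 and -0.18, and another probe set of ctnnb1.L at 0.15. Group means lay between 2.66 and 3.58 for both esr1 copies, both sox3 copies, emx2.L, gata4.S and capn5.L, low against array medians of 5.25 to 5.31. Signal over background was not measured, so small differences of these genes do not show that the 2 kinds of testis are alike. With 1 array left out, the sign changed for sox9.S and lhx9.L (0.06 and -0.11 without sex-reversed replicate 3), for ctnnb1.L, esr1.S and fst.L (0.11, -0.03 and -0.16 without normal replicate 2) and for sox3.L (-0.08 without normal replicate 3). It also changed for cbx2.L (0.10 without sex-reversed replicate 1) and esr1.L (0.13 without sex-reversed replicate 2). The female-determining gene dm-W and its relative dmrt1 were not analysed here, since no probe set carried either as its only symbol.

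Genes of the ovary and of estrogen response did not pass. The 34 oocyte and ovary genes were 15 higher and 19 lower (median -0.04, adjusted p = 0.840). The egg coat gene zp4.S differed by 1.07 (95% interval 0.26 to 1.88), from 5.33 ± 0.61 (SD, n = 3) in normal to 6.40 ± 0.33 in sex-reversed testis, and did not pass. The kinase gene wee1.S differed by -1.04 and the RNA-binding protein gene lsm14b.L by -0.73. Of 11 estrogen-responsive genes 7 were higher and 4 lower (median 0.10, adjusted p = 0.659). Differences were 0.47 for serpina1.L, -0.41 for serpina1.S and 0.40 for the transthyretin gene ttr.L. Group means of both serpina1 copies and ttr.L lay between 2.69 and 3.39, low against array medians of 5.25 to 5.31. Signal over background was not measured, so their small differences do not show the absence of an estrogen response. The egg yolk precursor genes vtga2.L and vtgb1.L differed by -0.27 and -0.11.

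Smooth muscle and peritubular genes were 12 higher and 1 lower in sex-reversed testis (camera adjusted p = 0.00169 over 24 lists). The list did not pass with a correlation between genes estimated from the data (adjusted p = 0.566 with an estimated correlation), nor in fry (adjusted p = 0.461), and without normal replicate 1 its adjusted p was 0.05001. The list's mean level lay between -0.342 and -0.126 on the normal arrays and between 0.131 and 0.398 on the sex-reversed ones, so that each of the 3 sex-reversed arrays lay above each normal one, as they also did for the skeletal muscle and interrenal lists, which did not pass. The members included tropomyosin tpm2.S (1.20; 0.73 without normal replicate 2 and 1.80 without normal replicate 1), the growth factor receptor gene pdgfra.L (0.95), calponin cnn1.S (0.91), the myosin genes myh11.S (0.62) and myl9.L (0.58), smooth muscle actin acta2.L (0.55) and transgelin tagln.L (0.50). Another probe set of pdgfra.L lay at -0.06, tagln.S was the lower member at -0.04, and no member passed by itself.

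Lists of neighbouring connective tissue, vessels and striated muscle did not pass. Mean log2 differences were 0.07 for 24 extracellular matrix genes, 0.17 for 11 endothelial genes and 0.16 for 20 skeletal muscle genes, beside 0.47 for the smooth muscle list. The matrix genes were 13 higher and 11 lower (median 0.10, adjusted p = 0.659). The collagen gene col6a1.L lay at 1.10 (95% interval 0.29 to 1.91), fbln1.L at -0.71 and fibronectin fn1.S at 0.51. Other probe sets of fn1.S lay between -0.28 and 0.32. Endothelial genes were 7 higher and 4 lower (median 0.11, adjusted p = 0.659), with the receptor gene tek.S at 0.92 (0.31 without normal replicate 2), the tight junction gene cldn5.L at 0.75 and the transcription factor gene sox18.S at 0.73. Skeletal muscle genes were 14 higher and 6 lower (median 0.07, adjusted p = 0.492). Their mean level reached 0.0127 on the normal arrays and began at 0.0496 on the sex-reversed ones. Troponin tnnc1.L differed by 0.88, the myosin light chain gene mylpf.L by 0.82 and tpm3.L by 0.65 (0.20 without normal replicate 1). With only the probe sets above the median level the skeletal muscle list, then of 7 genes, passed at the preset correlation, with an adjusted p of 0.00163. It did not pass there with an estimated correlation (adjusted p = 0.277 with an estimated correlation) or in fry (adjusted p = 0.336).

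**Figure D2:**
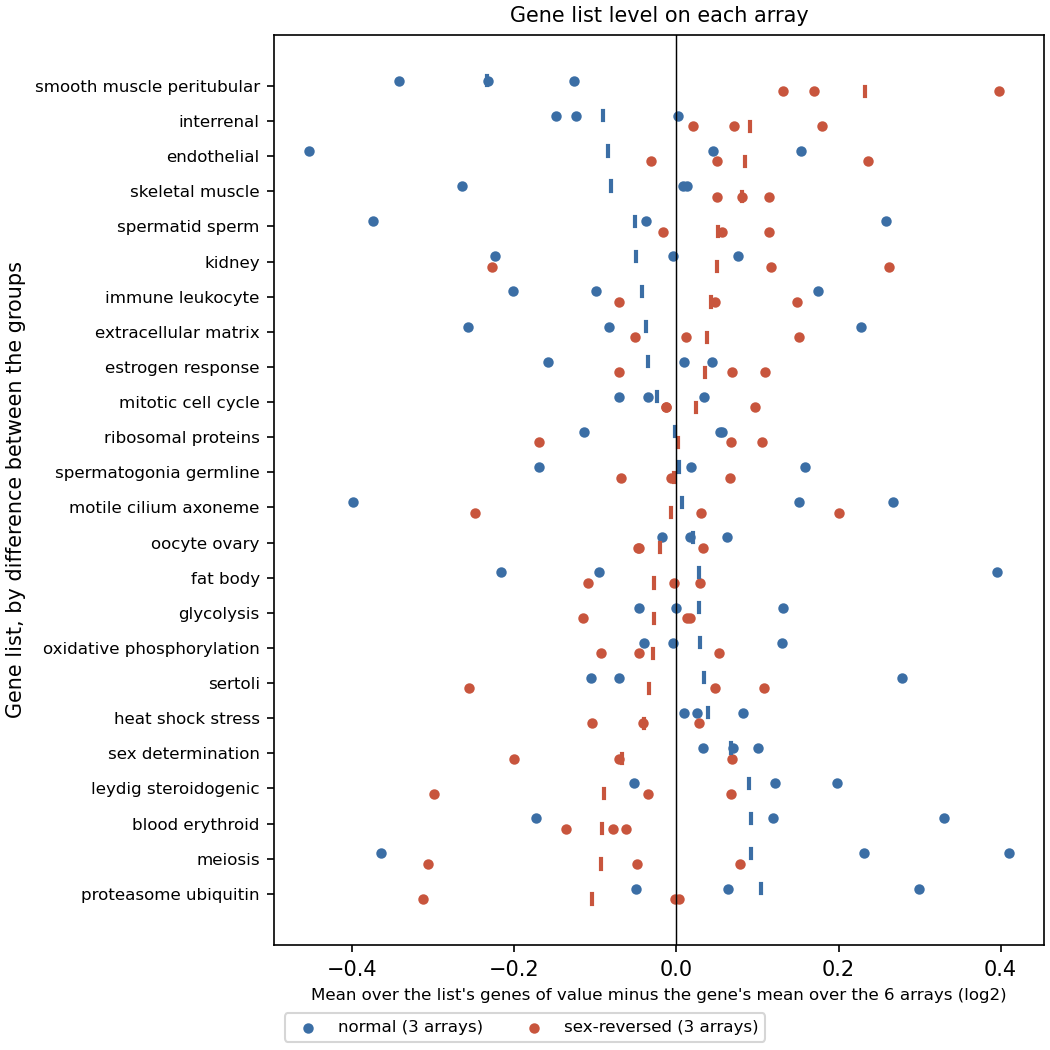
Mean over each list's genes of the log2 value minus the gene's mean over the 6 arrays (horizontal axis), for 24 lists ordered by the difference between the groups, 1 point per array and a bar at each group mean. For the smooth muscle list the normal arrays lie from -0.342 to -0.126 and the sex-reversed arrays from 0.131 to 0.398; the groups also lie apart for the skeletal muscle and interrenal lists, so in 3 of 24 lists, against 10% by chance.

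Markers of blood, immune cells and tissues that lie beside the testis did not pass either. Erythroid genes were 5 higher and 11 lower of 16 (median -0.13, adjusted p = 0.659), with ankyrin ank1.S at -0.99, the transcription factor genes nfe2.S at -0.98 and tal1.S at 0.88. Without sex-reversed replicate 3 nfe2.S lay at 0.07. Over all 6 arrays, other probe sets lay at 0.43, -0.28 and -0.28 for nfe2.S and at -0.24 for tal1.S. Of 17 leukocyte genes 12 were higher and 5 lower (median 0.13, adjusted p = 0.659), with the immunoproteasome gene psmb8.L at -0.90, complement factor cfb.S at 0.78 and the oxidase gene cybb.L at 0.68. Of 6 kidney genes 4 were higher and 2 lower (median 0.05, adjusted p = 0.659). Among them pck1.L lay at 0.60, pax2.L at 0.37 and fxyd2.S at -0.29 (0.24 without sex-reversed replicate 3). Other probe sets of pax2.L lay between -0.07 and 0.02. Of 11 fat body genes 4 were higher and 7 lower (median -0.10, adjusted p = 0.936), with the lipid droplet gene plin2.S at -0.71, cebpa.L at -0.66 (-0.19 without sex-reversed replicate 2 and -0.30 without normal replicate 2) and the desaturase gene scd.L at 0.49. The 6 genes of the interrenal gland, the frog's adrenal tissue, were 3 higher and 3 lower (median 0.17, adjusted p = 0.659), with neuropeptide Y copies npy.L at 0.71 and npy.S at 0.36 and the transporter gene slc18a2.L at 0.39.

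Genes used by most cells gave no list that passed. The 74 genes of the mitotic cell cycle were 47 higher and 27 lower (median 0.10, adjusted p = 0.658). Cyclin ccnb1.S differed by -2.20 with a 95% interval of -5.12 to 0.72, the spindle checkpoint gene bub1b.L by 1.44 (0.42 without sex-reversed replicate 3) and the DNA ligase gene lig1.L by -1.26. Ribosomal protein genes were 22 higher and 19 lower of 41, with a median of 0.03, a mean of 0.003 and a test in the lower direction (adjusted p = 0.892); rplp2.L lay at 1.56, rpl23a.S at -1.17 and rps23.L at -0.92. Without normal replicate 3 the value of rplp2.L was 0.13. Of 42 oxidative phosphorylation genes 19 were higher and 23 lower (median -0.01, adjusted p = 0.890), with sdhb.S at -1.80, atp5pd.S at -1.003 and atp5pb.L at 1.00. Without sex-reversed replicate 2 the value of sdhb.S was -0.01, and that of atp5pd.S ran from -1.80 without normal replicate 2 to -0.54 without normal replicate 1. Of 35 heat shock and stress genes 13 were higher and 22 lower (median -0.09, adjusted p = 0.659). Among them hspb1.S lay at -1.10, gpx1.S at 0.69 and hspd1.S at -0.65, with another probe set of hspd1.S at 0.09. Of 19 glycolysis genes 9 were higher and 10 lower (median -0.01, adjusted p = 0.890), with pfkp.L at -1.43, hk2.L at 0.72 and gapdh.L at -0.48. Proteasome genes were 9 higher and 19 lower of 28 (median -0.09, adjusted p = 0.658), with psma2.L at -0.76 and psmc5.S at -0.61 (-0.05 without normal replicate 1). The proteasome ATPase gene psmc1.L differed by -2.64 (95% interval -4.38 to -0.91), and its other probe set by -1.31; it passed without sex-reversed replicate 3, with an adjusted p of 0.0322 in limma against 0.0322 to 1.00 over 16 alternatives. In each of the 24 lists 0 members passed in limma over all probe sets and 0 when adjusted over the list alone, and members with an unadjusted p under 0.05 numbered 0 to 3 per list.

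Single genes with the strongest evidence in each direction were 10 higher and 10 lower in sex-reversed testis, and none of them passed. After ube3c.S, the higher ones were the iron-sulphur scaffold gene iscu.L (log2 difference 1.24), the cohesin gene rad21.S (1.16), ctps2.L (1.15), which makes CTP, and mos.L (1.15), a kinase known from egg maturation. The protease inhibitor gene serpine2.S and cat.2.L both differed by 1.01, cntn4.S by 0.94, mig30.L by 0.89 and tmem126a.L by 0.79. After cdca7l.S, the lower ones were dynll1.S (-2.17), a dynein light chain gene, gemin8.S (-1.94), of the complex that assembles splicing particles, and apex1.L (-1.76), a DNA repair nuclease. They were followed by hebp2.S (-1.57), fundc1.S (-1.46), sptlc1.L (-1.11), the angiotensin receptor gene agtr1.L (-1.07), prtn3.S (-0.91) and fadd.S (-0.86). Apart from ube3c.S and cdca7l.S, the adjusted p of these genes in limma was 0.615 or more. Among them, rad21.S in normal testis (3.05) and prtn3.S (2.68) and fadd.S (2.83) in sex-reversed testis had low group means. Array medians were 5.25 to 5.31 and signal over background was not measured, so the size of these differences is uncertain. The table held 24 other probe sets for 11 of these 20 genes. None of the 24 had an unadjusted p under 0.05 in the same direction in limma, and for 21 the 95% interval excluded the difference of the first probe set. The other probe set of ube3c.S differed by -0.40 (95% interval -1.08 to 0.28), and cdca7l.S had no other.

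Some probe sets varied widely between samples of 1 group, and the genes named for this were chosen after their values were seen. Over the 6 arrays 98 probe sets ranged at least 16-fold, 73 of them with exactly 1 gene symbol. The integrin-linked kinase gene ilk.S read 2.38 in normal replicate 3 and 7.86 to 8.84 on the other arrays. The succinate dehydrogenase gene sdhb.S read 3.08 in sex-reversed replicate 2 and at least 7.75 elsewhere. A probe set of the splicing factor gene srsf2.L read 9.21 in sex-reversed replicate 3 and 3.38 to 4.18 elsewhere. Another probe set of srsf2.L ranged over 0.633 on the log2 scale, around a mean of 10.9.

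**Figure D3:**
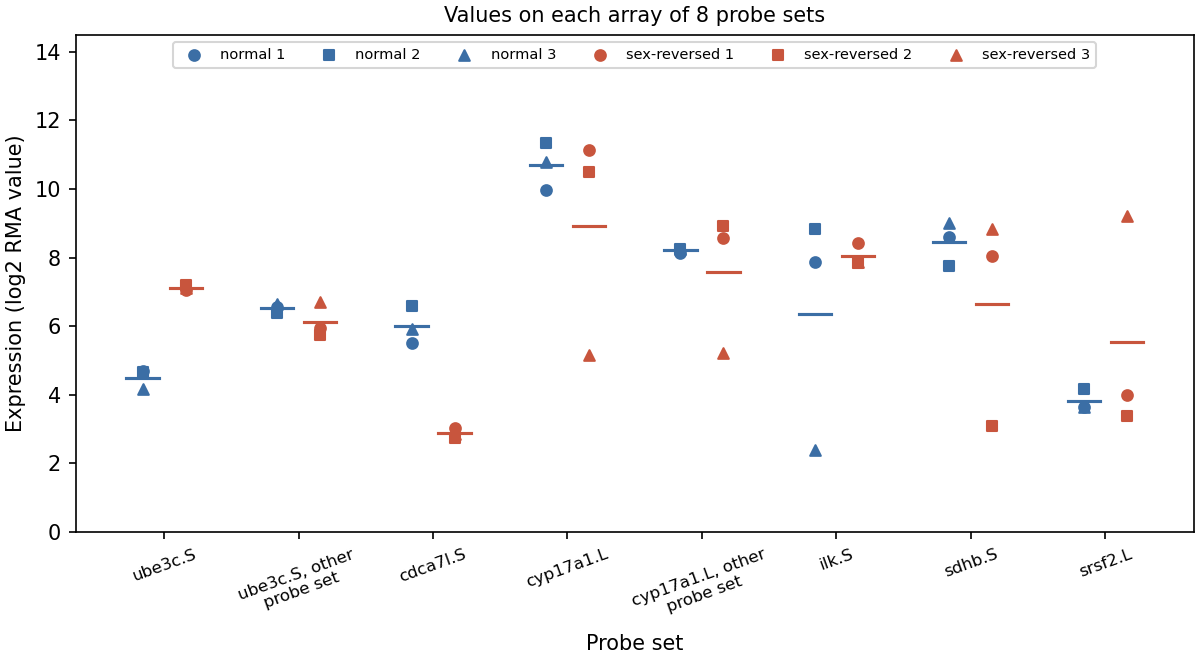
Log2 RMA values (vertical axis) of 8 probe sets on each of the 6 arrays, normal in blue and sex-reversed in red, with a symbol for each replicate number and a bar at each group mean. The groups lie apart for ube3c.S and cdca7l.S but not for the other ube3c.S probe set, and 1 array stands apart from the rest for cyp17a1.L (both probe sets, at 5.17 and 5.23), ilk.S (2.38), sdhb.S (3.08) and srsf2.L (9.21).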

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

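The mean over L and S copies was the alternative chosen after seeing the data. The count of 0 calls held under 10 of 16 alternatives with limma at an adjusted p of 0.05. Median centring gave 2 calls and array weights 2, with ube3c.S and cdca7l.S as the calls; quantile normalization again, only probe sets above the median level and removal of cross-hybridising probe sets gave 1 each, ube3c.S; a threshold of 0.1 gave 2. Every one of these calls also exceeded 2-fold. The main adjusted p of 0.0510 lay so near the threshold that small changes crossed it; over the alternatives it ran from 0.0325 to 0.610 for ube3c.S and from 0.0429 to 0.938 for cdca7l.S. Leaving out 1 array gave 0 to 6 calls, the 6 without sex-reversed replicate 3, where unadjusted p under 0.05 numbered 640; the cause was not tested. Those 6 were etfb.L (log2 difference 3.71), eef1a1.S (4.21), psmc1.L (-3.60), kansl2.S (-3.78) and 2 probe sets with no symbol. Intervals within 2-fold numbered 3545 with the filter at the median level, where 5742 probe sets were tested (61.7%). With the filter at the 25th percentile they numbered 4820 of 8613 (56.0%), and with the unmoderated test 5631 (49.0%). There were 998 at 1.5-fold and 5521 to 6167 with 1 array left out. The smooth muscle list passed under 16 of 19 alternatives (adjusted p 0.000495 to 0.566), at 0.000621 with the mean over copies. It did not pass with an estimated correlation (0.566, 0 lists), in fry (0.461, 0 lists) or without normal replicate 1 (0.05001, 0 lists); leaving out 1 array gave 0.000495 to 0.05001 and 0 to 1 lists. Only probe sets above the median level gave 2 lists, the other being skeletal muscle (0.00163, and 0.277 with an estimated correlation), 1 of 423 values of other lists that passed. Leaving out 1 array gave a distance of between minus within groups from -0.0293 to 0.0160. Of 103 named genes 14 changed sign at least once, 4 of them with an absolute log2 difference of at least 0.5, and 8 of 1576 values passed. Replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at -0.00684, -0.0247 and 0.139, and 2 of 6 arrays correlated best with their own number. The replicate block gave 0 calls, 524 probe sets at an unadjusted p under 0.05, 7104 intervals within 2-fold and an adjusted p of 0.000852 for smooth muscle, and changed no other call. Signal over background was not given in the sources used here, so its limit on dim probe sets was not measured.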

Other observations

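The tests of the number of lists over the splits, of the correlation between smooth muscle genes, of connective tissue, of steroidogenic cells and of the binding of variable probe sets were chosen after the result was seen. The spread of the lists between arrays was not tested. On normal replicate 2 the mean level lay at -0.365 for meiotic genes, -0.374 for spermatid and sperm genes and -0.399 for genes of the motile cilium, the lowest of the 6 arrays in each list, and the same array had the lowest endothelial level (-0.453), the highest fat body level (0.396) and the lowest array weight (0.712). Normal replicate 3 reached 0.410 for meiotic and 0.258 for spermatid genes. In the lists of meiosis, spermatids, the motile cilium and spermatogonia, the levels of the sex-reversed testes all lay between the lowest and the highest normal testis, from -0.0163 to 0.114 for spermatid genes and from -0.307 to 0.0783 for meiotic genes. Such containment held for 8 of 24 lists, and its share by chance was not computed. In the lists of meiosis, spermatids, the motile cilium and spermatogonia (-0.169), normal replicate 2 alone set the lower bound. Containment therefore does not show that the 2 kinds of testis are alike.

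The smooth muscle list was the single list past the threshold at the preset correlation, and it did not pass with an estimated correlation (adjusted p = 0.566, 0 lists) or in fry (adjusted p = 0.461). The real grouping gave a camera p of 7.02e-05 and the smallest p among the 9 other splits was 0.0155, so 1 of 10 splits gave a p as small, but 10 splits are too few for a share under 0.05. By the number of lists called, 5 of 10 splits gave as many as the 1 of the real grouping, and the highest other split gave 2. Genes of the list may vary together between animals: their estimated correlation was 0.0332 with a jackknife standard error of 0.0465, the call would be lost above 0.0726, and held at 0.0332 the adjusted p was 0.00896, so 6 arrays are too few to decide. More connective tissue in the sex-reversed pieces stays open too, since the smooth muscle level minus the matrix level was 0.392 higher in sex-reversed testis without separating the arrays (exact two-sided permutation p = 0.2, smallest possible 0.1). A difference that comes with sex reversal itself stays open, untested.

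A second pattern was a set of probe sets that read high on some arrays and low on others. With 0 calls in the real grouping, each of the 10 splits gives at least as many by construction, so that count tests nothing. The highest other split gave 7. The smallest adjusted p in limma was 0.0510 in the real grouping, that of ube3c.S. In the 9 other splits it was 0.000486, 0.00239, 0.00285, 0.00653, 0.0137, 0.0242, 0.444, 0.570 and 0.998. An adjusted p as small as that of ube3c.S thus also arose in groupings that mix the 2 kinds of testis. A gap of at least 2-fold between the groups was found for 6 probe sets, 6 of the 10 splits gave as many and the highest other gave 22, in a design that cannot give a share under 0.05. The groups held 18.68% of the variance of the 98 probe sets ranging at least 16-fold, and 5 of 10 splits held as much. The median share over the 10 splits was 18.28% (range 15.82% to 26.29%), so the real grouping did not stand out. A small part of the group cannot be excluded. For ube3c.S, a difference in probe binding, as from a sequence variant, is a candidate explanation that its other probe set, at -0.398, cannot decide. The first probe set was picked for the smallest p of all, and an extreme of noise would leave another probe set apart as well. For 21 of 24 other probe sets of the 20 genes with the strongest evidence, the 95% interval likewise excluded the first difference. Transcript forms that only 1 probe set detects were not tested, and cdca7l.S had no other probe set. For the variable probe sets binding and RNA level cannot be told apart. Other probe sets of the same genes followed with a median correlation of 0.101 over 17 pairs, against 0.166 over all 1424 pairs of probe sets of a gene. Where the other probe set lay above the median level the median was also 0.101, against 0.309 over all pairs with both above it. In the other direction, 6 of the 17 pairs (35.3%) reached 0.5 or more, against 26.3% of all pairs. Among the 6 were those of psmc1.L (0.976) and cyp17a1.L (0.958) and a pair of zbtb33.S (0.852), while another pair of zbtb33.S correlated at -0.403. The probe sets of the psmc1.L pair and of the zbtb33.S pair at 0.852 differ only in the suffix of their names. They may share sequence, so their correlation is not independent evidence of RNA level.

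The third pattern was the low cyp17a1.L on sex-reversed replicate 3, 27.7-fold under the lowest other array in one probe set and 7.51-fold in the other. On that array 7 probe sets lay at least 8-fold under all other arrays. There were 10 such probe sets on normal replicate 2, 5 on normal replicate 3, 3 on sex-reversed replicate 2, 1 on normal replicate 1 and 0 on sex-reversed replicate 1. The array with more, normal replicate 2, had the lowest array weight (0.712), so being exceeded by it decides nothing. The array weight of sex-reversed replicate 3 was 0.989, and a generally poor array stays open for it. Fewer steroidogenic cells on that array could account for it: the other 13 genes of the list deviated by a median of 0.08, but 0 of the 7 genes used by few other cells were measured, so this stays open. No other explanation was tested for this array.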
